A study of Homo sapiens with 10 samples.

How the data were processed

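Total RNA from HLE cells was labelled with a single dye and hybridised to Agilent whole-genome expression arrays, 1 array per sample, 10 arrays in 5 groups of 2. The groups were the negative control, miR-449a, miR-449b, miR-449c and the mixture of the 3 mimics, taken from the labels. Per the labels' protocols, RNA of 3 biological replicates was pooled for each array. Per the file headers, the scanner images were read with Agilent Feature Extraction 11.0.1.1, which gives each spot's background-corrected intensity on a linear scale, not normalized between arrays. Per the file names the arrays lay on 2 slides, with the control and the single mimics on the first and both mixture arrays on the second, scanned separately, so that slide and mixture cannot be told apart.

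Each array's background-corrected intensity was taken to log2 and the 75th percentile over its non-control spots was subtracted. Control spots and spots marked as outliers were left out, and spots of one probe were averaged. Of 50599 probes, 30878 carried a RefSeq accession and 28174 of these were named through a table of RefSeq genes (assembly GRCh38.p14). The other 22425 kept the name of the array design, which follows another genome build, so coordinates are not used here. Of several probes of a gene the one with the highest mean signal over all arrays stands for it, and the text says where another detected probe of a named gene disagrees. A gene was tested where its probe was well above background on both arrays of at least 1 group. This left 21542 of 41174 gene names, 14557 of them with a gene symbol, and 18603 well above background on all arrays. Signal over background is the depth of such data: 51.2% to 59.2% of the spots on an array were well above background.

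Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 10 arrays, with a mean per group and moderated variances (5 residual and 2 prior degrees of freedom). P-values were two-sided and adjusted by the Benjamini-Hochberg method within each of 9 comparisons, with a threshold of 0.05. The 9 comparisons were each mimic and the mixture with the control, the mean of the single mimics with the control, the 3 pairs of single mimics, and the mixture with the mean of the single mimics. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, and adjusted over the 16 lists within a comparison. The lists were reported miR-34 and miR-449 targets, S phase, G2/M, p53 targets, TGF-beta, mesenchymal, epithelial, Notch, interferon, hepatocyte, multiciliated cell, apoptosis, cholesterol synthesis, integrated stress, microRNA pathway and markers of other cell types. The target list includes SOX4, which the study's own authors may have chosen on these samples, so that member is not independent evidence.

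Genes are named by a rule. For comparisons with the control these are the 10 largest falls and the 10 largest rises. A named gene had to pass the threshold, have a gene symbol, be well above background on every array of the brighter group, and have all mimic arrays (or group means) on one side of the control arrays. For contrasts between mimics and with the mixture the 5 largest in each direction are named, members of the lists may be named besides, and CDC20B is always given. The comparisons, the lists, the naming rule and all alternatives but the row of the slide were fixed before the data were examined. The fit and the list test were tested on simulated data for miR-449a against the control, with 200 changed genes among 21542. Of genes changed by 2, 1 and 0.5 on the log2 scale, 92.5%, 62.7% and 15.2% were recovered, and 5 of 21306 unchanged genes were called. The measured comparison called 6102 genes, many more than were changed here, so these shares need not apply to it. The list shifted by -0.25 was called, and none of the other 15. Genes were simulated independently of each other, so the list test was not tried on genes that vary together.

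Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, no filter, a filter for all arrays, the mean of a gene's probes, a trended and robust prior, only the arrays of the groups compared, no mixture arrays, the replicate number as a block, and leaving out each array in turn. Normexp used the median spot signal in place of the mean. The deposited value table holds log2 values that the authors centred on each probe's median over the arrays, as its values show; how arrays were scaled is not given in the sources used here, and it was used as an alternative. Seed matches in 3' untranslated regions were not analysed here. Figures show values computed as above.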

Results

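Gene expression was profiled in HLE cells, a human cell line established from a hepatocellular carcinoma, after transfection with synthetic mimics of the microRNA-449 family. A mimic is a short double-stranded RNA that stands in for the mature microRNA. The microRNAs miR-449a, miR-449b and miR-449c are encoded together within an intron of the gene CDC20B. Both miR-449a and miR-449b share their seed sequence with the miR-34 family. An extra base at the start of miR-449c shifts its seed. Cells received 50 nM of a single mimic, 50 nM of a negative control small RNA, or an equimolar mixture with 16.7 nM of each mimic, and RNA was taken after 48 h. There were 5 groups with 2 arrays each, 10 arrays in total, and every array carried RNA pooled from 3 biological replicates. Between 51.2% and 59.2% of the 58717 non-control spots per array were well above background, and no spot was saturated. The probe for CDC20B was not well above background on any of the 10 arrays.

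All changes below are fitted log2 fold changes with their standard error (SE), from 2 arrays per group, and the number of arrays limits their precision. The labels do not say whether the pools on the arrays of one group came from different cultures, so the p-values may measure only technical spread. Replicate arrays differed from each other with a standard deviation across genes of 0.50 in the control, 0.33 with miR-449a, 0.35 with miR-449b, 0.34 with miR-449c and 0.38 with the mixture. No gene had identical values on the arrays of any pair. Where a group was not well above background, the change is given as a bound ("at least N-fold"). That bound sets the mean of the brighter group against the higher of the dim signal and the lowest signal well above background on each array.

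**Figure D1:**
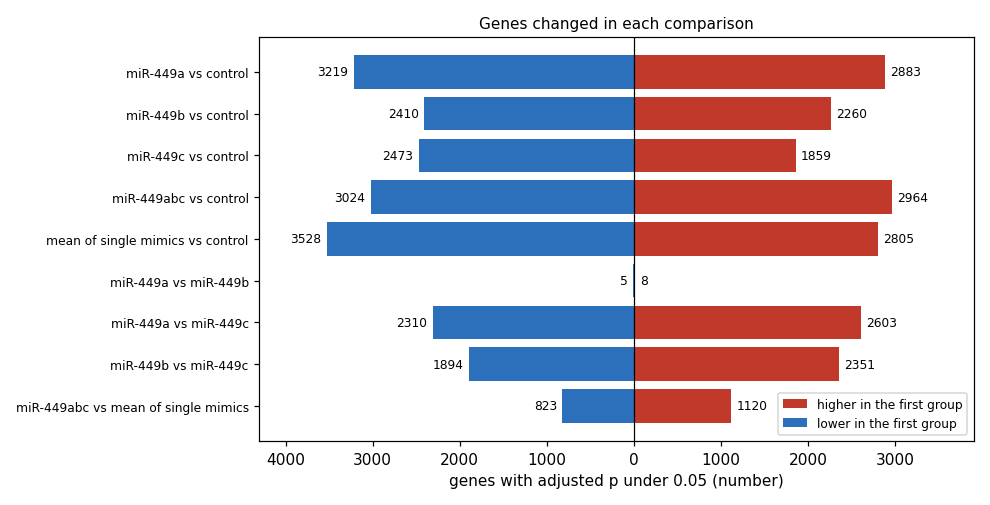
Number of genes with an adjusted p under 0.05 (horizontal axis, number of genes) in each of 9 comparisons (vertical axis), with genes higher in the first group to the right and lower genes to the left. The contrast of miR-449a with miR-449b has 8 higher and 5 lower genes, against 2603 and 2310 for miR-449a with miR-449c.

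The first question was which transcripts differed after miR-449a. E2F5, a transcription factor of the E2F family, fell by 2.50 (SE 0.11, adjusted p = 0.000334), and AMOT, an angiomotin of the Hippo pathway, fell by 2.45 (SE 0.43). MATN3 (-2.30, SE 0.63), KLHDC8B (-2.28, SE 0.56) and SYT1, a synaptic vesicle protein (-2.25, SE 0.31), fell as well. The control arrays differed widely for MATN3 and KLHDC8B: MATN3 was at -3.19 without control replicate 1 and at -1.42 without control replicate 2, where it did not pass (adjusted p = 0.108). KLHDC8B was at -3.28 without control replicate 1 and at -1.28 without control replicate 2. Among genes measured in both groups, SPEF1, a microtubule-binding protein of motile cilia, rose by 3.22 (SE 0.17, adjusted p = 0.000367). The antisense transcript PLCE1-AS1 rose by 3.18 (SE 0.13), the chemokine CCL5 by 3.14 (SE 0.11), SOWAHD by 3.09 (SE 0.17) and the chemokine CX3CL1 by 2.96 (SE 0.20).

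Several of the largest changes with miR-449a involved genes that were not well above background on the other side. The noncoding RNA EGOT was at least 7.63-fold higher (adjusted p = 0.000367), DNAI7, a component of axonemal dynein, at least 6.57-fold higher (adjusted p = 0.000565), and LCA5L at least 4.21-fold higher (adjusted p = 0.00671). The protease gene ADAMTS5 was at least 2.29-fold higher (adjusted p = 0.00933) and the axonemal dynein heavy chain gene DNAH7 at least 2.12-fold higher (adjusted p = 0.00276). In the other direction the noncoding RNA HAGLR was at least 4.96-fold lower (adjusted p = 0.000485) and BRME1 at least 3.19-fold lower (adjusted p = 0.0364). The SE of BRME1 was 0.71 on the log2 scale, and its fitted value was -2.38 or -2.74 without control replicate 1 or 2. MYB, a transcription factor, was at least 2.72-fold lower (adjusted p = 0.0303), the pseudogene LAMB2P1 at least 2.33-fold lower (adjusted p = 0.00638) and NFE2 at least 2.17-fold lower (adjusted p = 0.0194). Their fitted log2 values depended on single arrays. The calls of BRME1, MYB and NFE2 rest on all arrays and did not hold in each fit with an array left out. Leaving out miR-449a replicate 1 or 2 gave -3.46 or -2.38 for MYB and -1.5 or -3.04 for NFE2. Leaving out control replicate 1 or 2 gave -4.18 or -2.46 for LAMB2P1.

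Of 39 measured genes reported as targets of miR-34 or miR-449, 25 fell, 2 rose and 12 did not pass with miR-449a; adjusted over the list alone, 26 fell and 2 rose. The cell cycle kinase genes CDK6 and CDK4 fell (-1.51, SE 0.10, and -1.36, SE 0.24), as did the receptor gene MET (-1.78, SE 0.20), the small GTPase gene RRAS (-2.07, SE 0.23) and SOX4 (-1.1, SE 0.17). The receptor gene PDGFRB rose by 1.39 (SE 0.12). Of 43 S phase and DNA replication genes, 34 fell and none rose, and adjusted over the list alone 39 fell. Examples are the replicative helicase subunit MCM3 (-1.29, SE 0.13) and E2F2 (-1.51, SE 0.13). Of 36 genes of G2/M and mitosis, 27 fell and none rose, with 28 falls adjusted over the list alone. Among them were HMMR (-0.88, SE 0.09), ECT2, which acts in cytokinesis (-0.78, SE 0.07), and the mitotic kinase PLK1 (-0.63, SE 0.12). The set test camera with its preset correlation gave adjusted p = 6.38e-07 for the target list, 3.04e-13 for S phase and 3.45e-08 for G2/M. With an estimated correlation these became adjusted p = 0.203, 0.129 and 0.203, so none of these 3 calls held there.

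Among 18 apoptosis regulators 7 rose and none fell with miR-449a, and 8 rose and 1 fell adjusted over the list alone. The inhibitor of apoptosis BIRC3 (2.23, SE 0.36) and MCL1 (0.55, SE 0.13), which restrain cell death, were among those that rose. BAK1 (0.83, SE 0.18) and BBC3 (0.65, SE 0.14), which promote it, also rose. BIK, which promotes it too, passed as higher (adjusted p = 0.0116), with the control not well above background. The list had camera adjusted p = 0.0136, and adjusted p = 0.203 with an estimated correlation. Of 24 p53 target genes 9 rose and 1 fell, with GADD45A, a stress-induced gene, up by 1.76 (SE 0.23) and CCNG1 down (-0.94, SE 0.17). Adjusted over that list alone, 9 rose and 2 fell. Its adjusted p was 0.0394 with camera, 0.203 with an estimated correlation, 0.102 without miR-449a replicate 1 and 0.0519 without control replicate 1. Of 17 genes of the integrated stress and unfolded protein response 5 rose, among them SLC7A11 (1.17, SE 0.15), and XBP1 fell by 0.51 (SE 0.08); adjusted over the list alone, 8 rose and 2 fell. Camera gave adjusted p = 0.00741 there, and adjusted p = 0.295 with an estimated correlation.

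Of 20 cholesterol synthesis genes 7 fell and none rose with miR-449a, 8 adjusted over the list alone, and their transcriptional regulator SREBF2 fell by 1.20 (SE 0.15). Of 25 interferon and double-stranded RNA response genes 5 rose and 1 fell, and 9 rose and 3 fell adjusted over the list alone; the RNA sensor RIGI rose by 0.84 (SE 0.14) and the antiviral enzyme OAS2 by 0.86 (SE 0.13). Camera gave adjusted p = 0.0136 for cholesterol synthesis and 0.00741 for the interferon list, against adjusted p = 0.647 and 0.538 with an estimated correlation. The cholesterol call was also lost without control replicate 2 (adjusted p = 0.244) or miR-449a replicate 1 (0.0575). The interferon call was lost without control replicate 1 (adjusted p = 0.058) or miR-449a replicate 2 (0.0925). Of 8 measured markers of leukocytes, erythroid and endothelial cells, 2 fell (3 adjusted over the list alone), none rose and 6 did not pass, with the largest fall in CD68, a lysosomal protein (-1.34, SE 0.10). Their camera adjusted p was 0.0394, with adjusted p = 0.368 with an estimated correlation, and 0.195, 0.0509 and 0.0572 without control replicate 1, miR-449a replicate 1 and miR-449a replicate 2.

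The remaining 7 lists had no camera call with miR-449a. Of 30 TGF-beta genes 8 rose and 5 fell (8 and 6 adjusted over the list alone), among them THBS1 (1.90, SE 0.15) and CCN2 (2.03, SE 0.27), both secreted matrix-associated proteins, and TGFBR2 (-0.51, SE 0.13). Of 12 mesenchymal genes 3 rose (3 rose and 1 fell adjusted over the list alone), and of 13 epithelial genes 2 rose and 3 fell (3 and 3 adjusted over the list alone), with the tight junction gene CLDN1 up by 2.24 (SE 0.20). Of 16 Notch pathway genes 1 rose and 2 fell (0 and 1 adjusted over the list alone), of 7 hepatocyte genes 2 fell (2 adjusted over the list alone), and of 10 multiciliated cell genes 1 rose and 2 fell (2 and 2 adjusted over the list alone). Of 13 microRNA pathway genes 2 rose and 5 fell, the same counts as over the list alone, and DICER1, which cuts microRNA precursors, fell by 0.79 (SE 0.08).

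In total, 2883 of 21541 tested genes were higher and 3219 lower with miR-449a than in the control (limma, adjusted p under 0.05), of which 446 and 554 changed at least 2-fold. The share of higher genes was 47.2%, and 58.6% after quantile normalization. The 6102 calls became 2566 with no filter on dim probes and 2332 when only the arrays of these groups were fitted. Without miR-449a replicate 1, miR-449a replicate 2 or control replicate 1 there were 2563, 3381 and 3788.

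**Figure D2:**
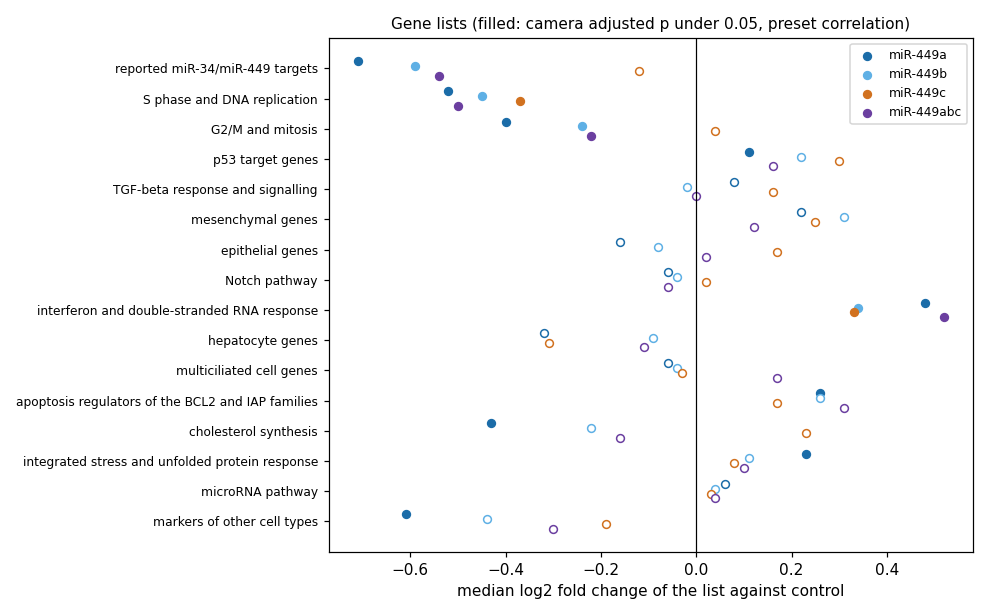
Median log2 fold change against control (horizontal axis) of the measured members of 16 gene lists (vertical axis) for each mimic and the mixture (colours), with filled points where camera with its preset correlation gave an adjusted p under 0.05. The S phase list lies at -0.52, -0.45, -0.37 and -0.50 with miR-449a, miR-449b, miR-449c and the mixture, while the G2/M list lies at 0.04 with miR-449c.

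With miR-449b the changes involved many of the genes named for miR-449a. SOWAHD rose by 3.18 (SE 0.17) and SPEF1 by 3.01 (SE 0.17), both at adjusted p = 0.000769. DNAI7 was at least 6.78-fold higher (adjusted p = 0.000999), EGOT at least 4.17-fold (adjusted p = 0.000769), LCA5L at least 3.38-fold (adjusted p = 0.0131) and CFAP57, a cilium and flagellum protein, at least 3.15-fold (adjusted p = 0.00931). The glucose transporter gene SLC5A1 was at least 2.44-fold higher (adjusted p = 0.00511), ADAMTS5 at least 2.14-fold (adjusted p = 0.0138) and DNAH7 at least 1.84-fold (adjusted p = 0.00526). SLC9C1 was at least 12-fold higher (adjusted p = 0.0456), with an SE of 1.40 on the log2 scale and an SD of 1.75 between the miR-449b arrays. Leaving out miR-449b replicate 1 or 2 gave a fitted value of 3.73 or 6.2 on that scale, and the call held in neither fit. The miR-449a arrays also differed widely for SLC9C1 (SD 3.2). ADAMTS5 stood at 2.93 or 3.52 without control replicate 1 or 2, and its call did not hold in each of these fits.

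The largest measured fall with miR-449b was that of CAV3, a caveolin (-3.35, SE 0.25, adjusted p = 0.00125). TNS1, a focal adhesion protein, fell by 2.30 (SE 0.25), although its other probe changed by -0.45 and did not pass. SLC45A3 fell by 2.00 (SE 0.14). Genes not well above background with miR-449b were NRN1 (at least 3.30-fold lower, adjusted p = 0.0476), ANGPT4 (at least 2.85-fold, adjusted p = 0.0336), LAMB2P1 (at least 2.13-fold, adjusted p = 0.0173) and TAS1R3 (at least 1.71-fold, adjusted p = 0.0278). Leaving out control replicate 1 or 2 gave fitted log2 values of -2.75 or -1.58 for NRN1 and -2.12 or -3.59 for ANGPT4. For LAMB2P1 these were -3.56 or -1.84, and for TAS1R3 -2.97 or -1.43. TXNIP, which binds thioredoxin, was at least 1.69-fold lower (adjusted p = 0.0156), ZC3H6 at least 1.61-fold (adjusted p = 0.0197) and CCDC60 at least 1.41-fold (adjusted p = 0.0181). Leaving out miR-449b replicate 1 or 2 gave -1.81 or -3.05 for TXNIP and -1.72 or -2.87 for CCDC60 on the log2 scale. ZC3H6 stood at -3.32 or -2.07 without control replicate 1 or 2. The calls of NRN1, ANGPT4, TAS1R3, TXNIP, CCDC60 and ZC3H6 rest on all arrays and did not hold in each of these fits.

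Of the 39 reported targets 21 fell and 2 rose with miR-449b (24 and 3 adjusted over the list alone), including E2F5 (-1.95, SE 0.11), RRAS (-1.68, SE 0.23), MET (-1.41, SE 0.20) and CDK6 (-1.40, SE 0.10). Of 43 S phase genes 31 fell (32 adjusted over the list alone), and of 36 G2/M genes 12 fell (17 adjusted over the list alone). No member of either list rose. For these 3 lists camera gave adjusted p = 2.03e-06, 1.49e-11 and 4.08e-05, against adjusted p = 0.313, 0.171 and 0.313 with an estimated correlation. Of 25 interferon genes 4 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0242, adjusted p = 0.604 with an estimated correlation), and this call was lost without control replicate 1 (adjusted p = 0.164), without miR-449b replicate 2 (0.106) and after quantile normalization (0.0575). No other list had a camera call in this fit.

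In total 2260 genes were higher and 2410 lower with miR-449b, of which 303 and 383 changed at least 2-fold; the share of higher genes was 48.4%, and 59.5% after quantile normalization. In the fit of all arrays 8253 genes had an unadjusted p under 0.05. The 4670 calls became 1365 with no filter on dim probes and 0 when only the arrays of these groups were fitted. Without miR-449b replicate 1, miR-449b replicate 2 or control replicate 1 there were 1803, 1788 and 2274.

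With miR-449c another set of genes led. TNFRSF4, a receptor of the tumour necrosis factor receptor family, rose by 7.63 (SE 0.24, adjusted p = 4.01e-05), from a mean signal of -5.03 (SD 0.06) in the control to 2.60 (SD 0.59). AVP, which encodes the hormone vasopressin, rose by 6.13 (SE 0.56, adjusted p = 0.00129). The calmodulin-like gene CALML5 rose by 3.23 (SE 0.19), the activin-type receptor gene ACVR1C by 2.59 (SE 0.35), the transporter gene SLC6A18 by 2.56 (SE 0.13) and EFCAB12 by 2.29 (SE 0.09). CX3CL1 and the homeobox gene VAX1 both rose by 2.20 (SE 0.20 and 0.31), and IL1RAP, a subunit of the interleukin 1 receptor, rose by 2.19 (SE 0.07), while another IL1RAP probe changed by 0.27 and did not pass. The BCL2 family gene BIK, which promotes cell death, was at least 4.68-fold higher (adjusted p = 0.00236).

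The falls with miR-449c were led by LRRD1 (-4.38, SE 0.29), SPATA21 (-3.82, SE 0.24), PABPC3, a poly(A)-binding protein gene (-3.10, SE 0.09), and SLC45A3 (-2.60, SE 0.14). The homeobox gene HOXB2 was at least 4.03-fold lower on its brighter probe (adjusted p = 7.21e-05), while its other probe changed by -0.43 and did not pass. PRAMEF5 was at least 3.23-fold lower (adjusted p = 0.000167), IFNLR1, a receptor for type III interferons, at least 2.63-fold (adjusted p = 0.0242) and EDNRB, an endothelin receptor, at least 1.94-fold (adjusted p = 0.0484; control SD 1.72), which did not pass without control replicate 2 (adjusted p = 0.0975). KPLCE was at least 1.54-fold lower (adjusted p = 0.000214) and ZNF311 at least 1.30-fold (adjusted p = 0.000946). The other probe of IFNLR1 changed by -1.58 and did not pass. On its brighter probe IFNLR1 stood at -3.09 or -1.75 on the log2 scale without miR-449c replicate 1 or 2. Its call did not hold in each of these fits.

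Of the 39 reported targets, 8 fell, 4 rose and 27 did not pass with miR-449c (11 fell and 4 rose adjusted over the list alone), and camera gave adjusted p = 0.229. E2F5 (-1.90, SE 0.11), CDK4 (-1.85, SE 0.24), CDK6 (-1.67, SE 0.10) and the histone deacetylase gene HDAC1 (-0.99, SE 0.09) fell, whereas CD44 rose by 0.68 (SE 0.16). Of 43 S phase genes 26 fell and none rose (30 falls adjusted over the list alone), with camera adjusted p = 1.54e-09, and adjusted p = 0.25 with an estimated correlation. Of 36 G2/M genes 2 fell and 2 rose (1 and 1 adjusted over the list alone; camera adjusted p = 0.478). Of 25 interferon genes 7 rose and none fell (9 and 1 adjusted over the list alone), with TLR3, a sensor of double-stranded RNA, up by 1.15 (SE 0.21). That list had camera adjusted p = 0.00184, adjusted p = 0.652 with an estimated correlation, and 0.072 without control replicate 1.

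In total 1859 genes were higher and 2473 lower with miR-449c, of which 254 and 471 changed at least 2-fold; the share of higher genes was 42.9%, and 56.7% after quantile normalization. The 4332 calls became 1380 with no filter on dim probes and 313 when only the arrays of these groups were fitted. Without miR-449c replicate 1, miR-449c replicate 2 or control replicate 1 there were 1672, 2749 and 2491.

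**Figure D3:**
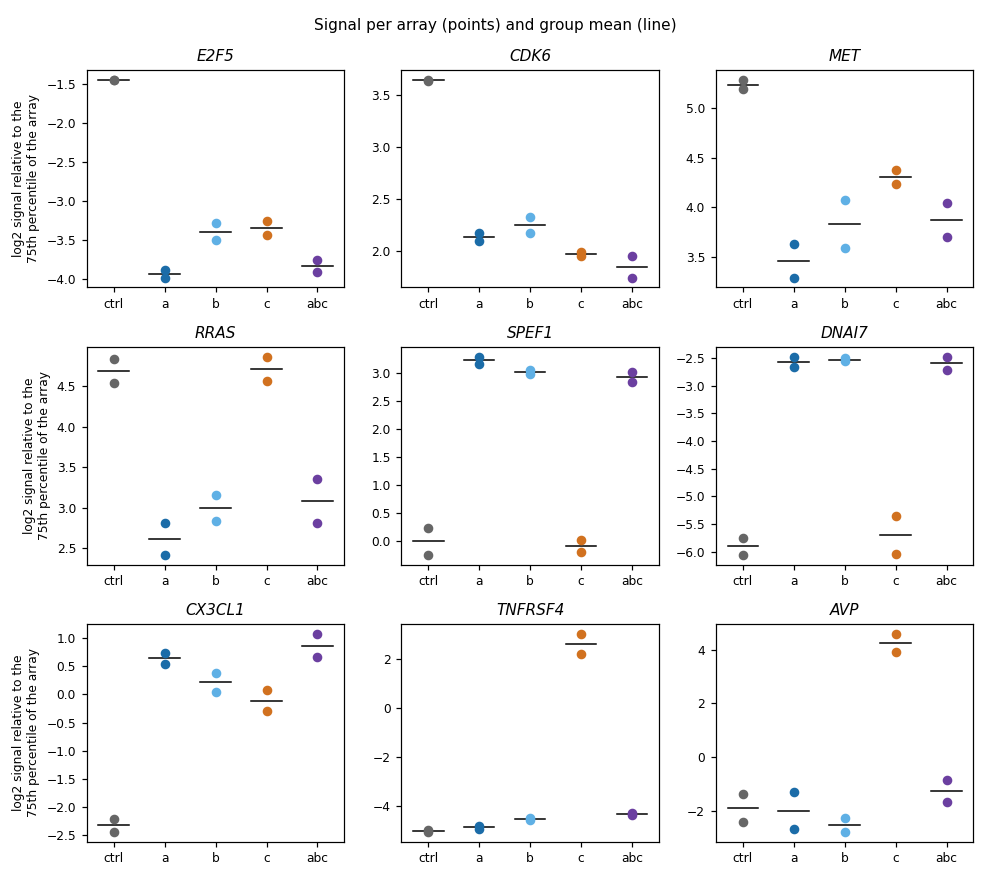
Signal of 9 genes on each array (points; vertical axis, log2 signal relative to the 75th percentile of the array) and group means (lines) for the control, the 3 single mimics and the mixture (horizontal axis). E2F5 and CDK6 lie below the control in every mimic group, SPEF1 and DNAI7 lie near the control with miR-449c alone among the mimic groups, and TNFRSF4 and AVP lie high with miR-449c.

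The single mimics were set against each other at the same dose and time. Between miR-449a and miR-449b few genes differed. CAV3 was higher with miR-449a by 3.12 (SE 0.25, adjusted p = 0.0177), FGF3, a fibroblast growth factor, by 1.19 (SE 0.12), the chemokine CCL20 by 1.16 (SE 0.08), ZNF257 by 0.91 (SE 0.09) and NUDT4 by 0.77 (SE 0.08). SMIM15 was lower with miR-449a (-1.03, SE 0.08, adjusted p = 0.0177). The other probes of ZNF257 and NUDT4 changed by 0.29 and 0.12 and did not pass. No member of any of the 16 lists passed by itself, whether adjusted over all genes or over the list alone. As sets, G2/M (median -0.15) and S phase genes (median -0.11) were lower with miR-449a by camera (adjusted p = 2.45e-08 and 3.23e-07), against adjusted p = 0.228 for both with an estimated correlation. The reported targets (median -0.09) and cholesterol genes (median -0.11) were lower and the stress response list (median 0.13) higher, with adjusted p = 0.0133, 0.0321 and 0.00893. With an estimated correlation these became adjusted p = 0.398, 0.748 and 0.368, and each was also lost without miR-449a replicate 1 (adjusted p = 0.208, 0.453 and 0.0854). The target and cholesterol calls were lost without miR-449b replicate 2 as well (adjusted p = 0.416 and 0.725), and the latter after quantile normalization (0.0589).

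In total 8 genes were higher and 5 lower with miR-449a than with miR-449b, while 1710 had an unadjusted p under 0.05. The 95% interval of a gene's difference, not adjusted for the number of genes, reached 0.31 to each side at the median SE. Smaller differences between these mimics stay open, and so do larger ones. In the simulated data for miR-449a against the control, 15.2% of changes of 0.5 and 62.7% of changes of 1 were recovered. The 13 calls became 5 without the mixture arrays (4 of them shared), 3 with no filter on dim probes and 0 with only the arrays of these groups, against 20 with normexp and 38 with a trended and robust prior. Leaving out one array gave between 2 (without miR-449a replicate 2) and 57 (without miR-449b replicate 1, 9 higher and 48 lower), with 21 without miR-449a replicate 1 (20 higher and 1 lower), 6 without either miR-449c array and 5 without either control array or either mixture array.

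Between miR-449a and miR-449c the differences were many. SPEF1 was higher with miR-449a by 3.30 (SE 0.17), LRRD1 by 3.90 (SE 0.29) and SPATA21 by 3.14 (SE 0.24), HOXB2 was at least 4.55-fold higher (adjusted p = 7.69e-05), with its other probe also higher (1.09), and PRAMEF5 at least 2.69-fold (adjusted p = 0.000184). TNFRSF4 (-7.48, SE 0.24), AVP (-6.24, SE 0.56), CALML5 (-3.90, SE 0.19) and the prostacyclin receptor gene PTGIR (-2.59, SE 0.26) were lower with miR-449a, and WWC3 was at least 5.24-fold lower (adjusted p = 0.0292). WWC3 stood at -2.27 or -4.56 on the log2 scale without miR-449a replicate 1 or 2. The former falls short of its bound, which is 2.39 on that scale, and the call did not hold in each of these fits. Of 36 G2/M genes 22 were lower with miR-449a than with miR-449c and none higher (29 adjusted over the list alone), among them HMMR (-0.82, SE 0.09) and TTK (-0.57, SE 0.07). Of the 39 reported targets 19 were lower and 2 higher (22 and 2 adjusted over the list alone), with RRAS (-2.09, SE 0.23), FOSL1 (-1.86, SE 0.15) and AXL (-1.27, SE 0.08) among them. CDK6 (0.16, SE 0.10, adjusted p = 0.287) and HDAC1 (-0.03, SE 0.09, adjusted p = 0.823) did not pass. Of 20 cholesterol synthesis genes 7 were lower and none higher (10 adjusted over the list alone), including SREBF2 (-1.42, SE 0.15). The microRNA-processing gene DICER1 was lower as well (-1.13, SE 0.08).

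Camera gave adjusted p = 4.95e-11 for G2/M, 0.00011 for the reported targets, 1.49e-05 for cholesterol synthesis, 0.000401 for S phase (11 lower, 2 higher; 12 and 2 adjusted over the list alone) and 0.00809 for the stress response list (6 higher, none lower; the same adjusted over the list alone). With an estimated correlation these became adjusted p = 0.248, 0.452, 0.6, 0.452 and 0.457. In total 2603 genes were higher and 2310 lower with miR-449a than with miR-449c, 488 and 388 of them at least 2-fold. The 4913 calls became 1813 with no filter on dim probes and 2841 with only the arrays of these groups. Without miR-449a replicate 1, miR-449a replicate 2, miR-449c replicate 1 or miR-449c replicate 2 there were 1961, 2579, 2361 and 2912.

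The contrast of miR-449b with miR-449c named many of the same genes. TNFRSF4 (-7.13, SE 0.24), AVP (-6.76, SE 0.56), CALML5 (-3.53, SE 0.19) and CAV3 (-2.57, SE 0.25) were lower with miR-449b, and WWC3 was at least 4.78-fold lower (adjusted p = 0.0258). WWC3 stood at -2.94 or -4.43 on the log2 scale without miR-449b replicate 1 or 2, and its call did not hold in each of these fits. LRRD1 was higher (3.90, SE 0.29), as were HOXB2 (at least 4.87-fold, adjusted p = 7.33e-05), PRAMEF5 (at least 2.83-fold, adjusted p = 0.000206), CFAP57 (at least 2.28-fold, adjusted p = 0.00577) and SLC9C1 (at least 8.72-fold, adjusted p = 0.043). SLC9C1 stood at 3.91 or 6.39 on the log2 scale without miR-449b replicate 1 or 2, and its call held in neither fit. Of 36 G2/M genes 15 were lower and 1 higher (22 and 1 adjusted over the list alone), of 39 reported targets 15 were lower and 2 higher (16 and 4 adjusted over the list alone), and of 20 cholesterol genes 6 were lower and none higher (7 adjusted over the list alone). The camera test gave adjusted p = 1.02e-06, 0.00256 and 0.00017, against adjusted p = 0.612, 0.838 and 0.838 with an estimated correlation. In total 2351 genes were higher and 1894 lower with miR-449b, 406 and 299 of them at least 2-fold. The 4245 calls became 1318 with no filter on dim probes and 1723 with only these arrays, and 1634, 1832, 1694 and 2404 without miR-449b replicate 1, miR-449b replicate 2, miR-449c replicate 1 and miR-449c replicate 2.

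**Figure D4:**
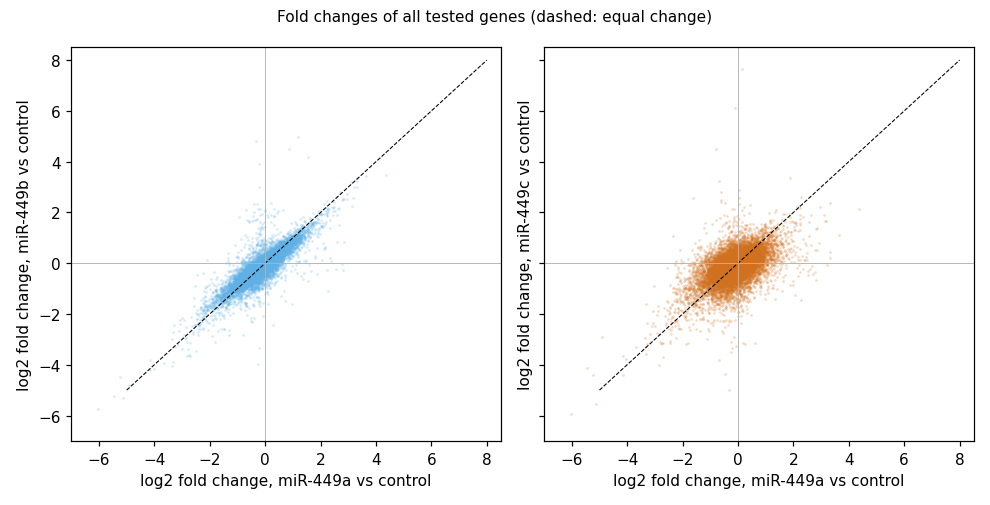
Log2 fold change against control of each tested gene with miR-449a (horizontal axes) and with miR-449b or miR-449c (vertical axes); the dashed line marks equal change. The correlation across genes is 0.87 for miR-449b and 0.55 for miR-449c. Beside these stands 0.50 for unchanged groups that share the control arrays, simulated with the same spread in every group.

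The mixture of the 3 mimics was compared with the control. SOWAHD rose by 3.24 (SE 0.17), CX3CL1 by 3.18 (SE 0.20), SPEF1 by 2.93 (SE 0.17) and PLCE1-AS1 by 2.84 (SE 0.13). DNAI7 was at least 6.45-fold higher (adjusted p = 0.00056), EGOT at least 5.59-fold (adjusted p = 0.000354), FANK1 at least 3.66-fold (adjusted p = 0.00504) and DNAH7 at least 2.20-fold (adjusted p = 0.0026). The olfactory receptor gene OR6C76 was at least 4.18-fold higher (adjusted p = 0.00269) and PDZD7 at least 1.76-fold (adjusted p = 0.00217). E2F5 (-2.39, SE 0.11) and SLC45A3 (-2.32, SE 0.14) fell. The small nucleolar RNAs SNORD15B (-2.69, SE 0.13) and SNORA74A (-2.46, SE 0.17) fell too, as did RNU12, a small nuclear RNA of the minor spliceosome (-2.52, SE 0.17). HAGLR was at least 4.22-fold lower (adjusted p = 0.000449), MYB at least 2.31-fold (adjusted p = 0.0413), LAMB2P1 at least 1.98-fold (adjusted p = 0.01), TXNIP at least 1.58-fold (adjusted p = 0.0138) and ZC3H6 at least 1.5-fold (adjusted p = 0.0257). Leaving out mixture replicate 1 or 2 gave -1.73 or -3.57 for MYB and -1.77 or -2.87 for TXNIP on the log2 scale. Leaving out control replicate 1 or 2 gave -2.93 or -1.69 for ZC3H6 and -3.79 or -2.07 for LAMB2P1. The calls of MYB, TXNIP and ZC3H6 did not hold in each of these fits. TNFRSF4, which had risen by 7.63 with miR-449c alone, stood at 0.70 in the mixture (SE 0.24, adjusted p = 0.0653) and did not pass.

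Of the 39 reported targets 22 fell and 2 rose with the mixture (23 and 2 adjusted over the list alone), with CDK6 (-1.80, SE 0.10), CDK4 (-1.78, SE 0.24) and RRAS (-1.61, SE 0.23) among them. Of 43 S phase genes 33 fell and none rose (37 and 1 adjusted over the list alone), and of 36 G2/M genes 13 fell and none rose (13 adjusted over the list alone). The set test gave adjusted p = 1.37e-06, 2.73e-14 and 0.000151, against adjusted p = 0.37, 0.11 and 0.436 with an estimated correlation. Of 25 interferon genes 10 rose and 2 fell, the same counts as over the list alone (camera adjusted p = 0.00653, adjusted p = 0.568 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.0663) or mixture replicate 2 (0.0837). In total 2964 genes were higher and 3024 lower, 395 and 535 of them at least 2-fold. The 5988 calls became 2470 with no filter on dim probes, 1692 with only these arrays, and 2881 and 3747 without mixture replicate 1 and 2. Both mixture arrays lay alone on a second slide, so slide and treatment cannot be told apart in any comparison of the mixture. Spike-in control probes were brighter on that slide by a median of 1.26 on the log2 scale.

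The mean of the single mimics was set against the control to ask what the family members did on average. SOWAHD (2.73, SE 0.14), CX3CL1 (2.57, SE 0.16), PLCE1-AS1 (2.48, SE 0.11), CCL5 (2.36, SE 0.09), ACVR1C (2.33, SE 0.28), the chemokine CCL11 (2.23, SE 0.21) and IL1RAP (2.13, SE 0.06) rose. PPARA, a nuclear receptor of lipid metabolism, rose by 2.23 (SE 0.10) on its brighter probe, while its other probe changed by 0.57 and did not pass. TNFRSF4 (2.76, SE 0.19) was among the rises through miR-449c, with 0.16 and 0.50 for miR-449a and miR-449b. BIK was at least 2.38-fold higher (adjusted p = 0.0026). SLC45A3 (-2.25, SE 0.11), KLHDC8B (-2.15, SE 0.45; -3.15 without control replicate 1 and -1.15 without control replicate 2) and E2F5 (-2.12, SE 0.09) fell. EDNRB passed as lower (adjusted p = 0.0408), but it was not above background with miR-449b or miR-449c, so no fold is given, and without control replicate 2 it did not pass (adjusted p = 0.182). NHEG1 was at least 9.12-fold lower (adjusted p = 0.0475) and the homeobox gene SHOX at least 6.29-fold lower (adjusted p = 0.048), with an SE of 1.44 and 0.87 on the log2 scale and control arrays that differed widely (SD 4.4 and 2.67). Leaving out control replicate 1 gave fitted log2 values of -7.83 and -4.72, and leaving out control replicate 2 gave -1.6 and -0.94. The latter fall short of the bounds, which are 3.19 and 2.65 on that scale. ANGPT4 was at least 2.58-fold lower (adjusted p = 0.0276), MYB at least 2.24-fold (adjusted p = 0.0288), LAMB2P1 at least 1.93-fold (adjusted p = 0.00811) and TXNIP at least 1.53-fold (adjusted p = 0.00845). Leaving out control replicate 1 or 2 gave -1.58 or -3.05 for ANGPT4 and -3.4 or -1.68 for LAMB2P1 on the log2 scale. The calls of NHEG1, SHOX and ANGPT4 did not hold in each of these fits.

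On average over the single mimics, 35 of 43 S phase genes fell (37 adjusted over the list alone), 23 of 39 reported targets fell and 2 rose (25 and 2 adjusted over the list alone), and 14 of 36 G2/M genes fell (17 adjusted over the list alone). Camera gave adjusted p = 5.93e-13, 3.54e-05 and 0.000341, against adjusted p = 0.135, 0.252 and 0.252 with an estimated correlation. Of 25 interferon genes 9 rose and 2 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.00131, adjusted p = 0.433 with an estimated correlation). Of 24 p53 targets 8 rose and 2 fell (8 and 5 adjusted over the list alone), and of 18 apoptosis regulators 6 rose and 1 fell (10 and 4 adjusted over the list alone). Their adjusted p was 0.0418 and 0.0382 with camera, and adjusted p = 0.252 for both with an estimated correlation; quantile normalization (0.0983 for both) ended both calls. In total 2805 genes were higher and 3528 lower, 247 and 362 of them at least 2-fold, and the share of higher genes was 44.3%, or 58.5% after quantile normalization. The 6333 calls became 2604 with no filter on dim probes and 2904 without control replicate 1.

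The mixture was last compared with the mean of the single mimics, which carry 50 nM of one mimic in place of 16.7 nM of each. Small noncoding RNAs were lower in the mixture: RNU12 (-2.56, SE 0.14), SNORD15B (-2.49, SE 0.10), SNORA74A (-2.18, SE 0.14), SNORA30 (-2.06, SE 0.21) and SNORA75 (-2.05, SE 0.15). OR6C76 was at least 4.06-fold higher (adjusted p = 0.0062), and TMEM176A (1.77, SE 0.40) and PLPPR3 (1.58, SE 0.35) were higher. The transcription factor gene DACH1 (adjusted p = 0.0445) and the nicotinic acid receptor gene HCAR2 (adjusted p = 0.0186) passed as higher too, with no fold given, since neither was above background with miR-449c. None of the 16 lists had a camera call in this fit, although the reported targets were called without mixture replicate 2 (adjusted p = 0.0029) or miR-449b replicate 1 (0.0347). Of the 39 reported targets 1 was higher and 1 lower, and of 43 S phase genes 2 were lower. In total 1120 genes were higher and 823 lower, 118 and 172 of them at least 2-fold. The share of higher genes turned from 57.6% to 33.0% after quantile normalization, 43.6% with normexp, 45.9% with median centring and 42.2% in the deposited value table. The 1943 calls became 301 with no filter on dim probes. They became 441 and 321 without mixture replicate 1 and 2, 760 and 905 without miR-449a replicate 1 and 2, 1146 and 938 without miR-449b replicate 1 and 2, and 1230 without miR-449c replicate 2. The second slide again holds only the mixture, so slide and treatment cannot be told apart here.

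The 4 comparisons with the control share its 2 arrays, which alone gives agreement between them. Among genes called against the control, E2F5 and CDK6 fell with every mimic and the mixture. Across all tested genes, 729 were higher and 660 lower in all 4 comparisons, and 44 were called in all 4 with differing directions. The correlation of fold changes across genes, which are not independent replicates, was 0.87 between miR-449a and miR-449b, 0.55 between miR-449a and miR-449c and 0.55 between miR-449b and miR-449c. With the mixture it was 0.68 for miR-449a, 0.67 for miR-449b and 0.57 for miR-449c. In 100 simulated sets of unchanged groups against the same controls the mean correlation was 0.50 for each pair. The simulation gave all groups the same spread per gene. Measured control arrays differed more from each other (SD 0.50) than those of the other groups (0.33 to 0.38). The simulated correlation and covariance may therefore be too low for these shared controls. The covariance was 0.256, 0.157 and 0.146 for the pairs of single mimics in that order, beside simulated values of 0.0287, 0.0289 and 0.0286, and 0.206, 0.188 and 0.156 for the pairs with the mixture, beside 0.0287, 0.0285 and 0.0287.

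Called genes overlapped in the same order. Between miR-449a and miR-449b 1991 genes were higher in both and 1937 lower in both, where independent lists would share 302 and 360, and 1 gene was called in opposite directions. Between miR-449a and miR-449c 995 were higher and 1106 lower in both (249 and 370 for independent lists), with 166 in opposite directions. Between miR-449b and miR-449c the counts were 871 and 864 (195 and 277), with 119 opposite. With the mixture, the counts were 1876 and 1772 for miR-449a (397 and 452), 1587 and 1455 for miR-449b (311 and 338), and 1122 and 1327 for miR-449c (256 and 347). The simulated unchanged groups shared between 0 and 0.04 called genes per pair on average, a value that leaves out real effects, as the independent lists leave out the shared controls. Part of the excess may come from the shared control arrays. How much was not tested, since a split of the control would leave 1 array on each side.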

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

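The tests in this part were chosen after the result was seen. Spike-in control probes, which enter no comparison between groups, were brighter on the slide of the mixture. Over 6 spike-in probes well above background on all arrays, the median difference between slide 2 (2 arrays) and slide 1 (8 arrays, the control among them) was 1.26 on the log2 scale, with single probes between 1.16 and 1.44. Within slide 1 the arrays spanned 0.22 in their median deviation.

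In the same arrays small nucleolar, Cajal body and spliceosomal RNAs were lower than with the single mimics, with a median of -0.42 over 257 genes, 122 lower and 4 higher. Against the control the median was -0.49 with the mixture (137 lower, 4 higher), -0.28 with miR-449c (88 lower, 21 higher), 0.05 with miR-449b (46 higher, 17 lower; -0.02 with normexp) and 0.19 with miR-449a (75 higher, 19 lower), so the single mimics differ among themselves. A slide, labelling or scan effect remains a candidate explanation, since slide and treatment cannot be told apart. The spike-in shift of 1.26 shows that the slides differ in spike-in signal. Before scaling, the 75th percentile of non-control signal was 976.9 and 942.0 on the mixture arrays, within the 897.4 to 1057.1 of slide 1. The spike-in shift alone therefore does not show a shift of transcripts. Whether the mixture shift of the small RNAs needs a difference between slides also stays open. On slide 1 these RNAs were higher with miR-449a than with miR-449c by a median of 0.45 (SE 0.03). That difference is not beyond the size of the mixture shift by more than 2 SE. The SE is across genes, which are not independent replicates. With quantile normalization the slide 1 difference and the mixture shift were 0.46 and -0.61, and with normexp 0.28 and -0.34.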

How the results depend on the processing

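1 alternative, the row of the slide as a block, was added after the data were seen. The 136 named results all kept their direction in every setting in which they were measured; 85 also kept their side of the threshold in all of them, and 345 single values lost it. Calls were lost most often when only the arrays of the groups compared were fitted (43 named results), with no filter on dim probes (37) and without control replicate 2 (25). Where leaving out an array leaves 1 in its group, that array is assumed to vary like the other groups.

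Counts moved by more than 1.5 times under these settings, and the cause was not tested except where fewer arrays, more genes or a size threshold is the setting itself. With no filter on dim probes they were 2566, 1365, 1380, 2470 and 2604 for miR-449a, miR-449b, miR-449c, the mixture and the mean of single mimics against control, 3, 1813 and 1318 for miR-449a with miR-449b, miR-449a with miR-449c and miR-449b with miR-449c, and 301 for the mixture with the single mimics. With a 2-fold threshold they were, in that order, 1000, 686, 725, 930, 609, 8, 876, 705 and 290. With only the groups compared they were 2332, 0, 313 and 1692 for the mimics and the mixture against control (for miR-449b, 8253 genes had an unadjusted p under 0.05 in limma's fit of all arrays), and 0, 2841 and 1723 for the 3 pairs. For miR-449a with miR-449b normexp gave 20, the trended and robust prior 38 and the arrays without the mixture 5.

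The labels number the arrays 1 and 2 in every group without saying that a number marks a shared batch; deviations of arrays of one number correlated by 0.03 to 0.30 over all pairs of groups and by 0.21 to 0.30 among the groups of slide 1, where the number is also the row of the slide. With the replicate block the counts were 7673 and 6906 for miR-449b and miR-449c against control, 20, 7644 and 7069 for the 3 pairs, and 4141 for the mixture with the single mimics, and within 1.5 times elsewhere. With the slide row as a block the last was 3342. The replicate block added camera calls for apoptosis (adjusted p = 0.0359) and cholesterol synthesis (0.0243) with miR-449b, for the stress response list with the mean of single mimics (0.0465), and for hepatocyte genes (0.0422) and apoptosis (0.031) in miR-449a with miR-449b. Quantile normalization added cholesterol synthesis with miR-449b (0.0263) and hepatocyte genes in miR-449a with miR-449b (0.048). Normexp added the stress response list in miR-449b with miR-449c (camera adjusted p = 0.0321).

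Leaving out one array gave 2563 to 5479 genes for miR-449a, 1788 to 4299 for miR-449b, 1672 to 3663 for miR-449c, 2881 to 5568 for the mixture and 2904 to 5612 for the mean of single mimics against control. It gave 2 to 57 for miR-449a with miR-449b, 1961 to 5076 for miR-449a with miR-449c, 1634 to 4317 for miR-449b with miR-449c and 321 to 2059 for the mixture with the single mimics. Among named genes measured in both groups, TMEM176A ranged from 1.1 to 2.43 and PLPPR3 from 1.02 to 2.14 in the last of these. Their calls did not hold in each of these fits. Camera calls that appeared in 1 or more of these fits, with the lowest adjusted p, were apoptosis (0.039), cholesterol synthesis (0.00413) and other cell types (0.0074) for miR-449b, cholesterol synthesis for miR-449c (0.00915), and apoptosis (0.0487), cholesterol synthesis (0.0151) and other cell types (0.0186) for the mixture. For the mean of single mimics they were cholesterol synthesis (0.0316) and other cell types (0.0145), for miR-449a with miR-449b interferon (0.00125), hepatocyte (0.0328) and Notch (0.0261), and for the mixture with the single mimics the reported targets (0.0029) and cholesterol synthesis (0.0499). Restricting to genes well above background on all arrays moved the correlation of fold changes to 0.92 for miR-449a with miR-449b, 0.72 for miR-449b with the mixture and 0.62 for miR-449c with the mixture. Quantile normalization moved the median of all genes from -0.08 to 0.02 with miR-449a. The estimated correlation ended every camera call of a list, and under no setting was a list's call reversed. Fry, which does not compare a list with other genes, gave S phase adjusted p = 6.09e-05 with miR-449a and 0.0756 for miR-449a with miR-449b. Fry ended the interferon calls (adjusted p = 0.121, 0.236, 0.161, 0.099 and 0.0788 for miR-449a, miR-449b, miR-449c, the mixture and the mean of single mimics), the cholesterol calls for miR-449a (0.0973) and for miR-449b with miR-449c (0.113), and the calls of all 5 lists for miR-449a with miR-449b. Fry also added calls that camera did not make. Among them were p53 targets with miR-449b, miR-449c and the mixture (fry adjusted p = 0.00287, 0.00193 and 0.00175). Others were apoptosis with miR-449b and the mixture (0.0208 and 0.00917) and reported targets with miR-449c (0.033). For miR-449a they included TGF-beta, mesenchymal, hepatocyte and microRNA pathway genes (0.0285, 0.0407, 0.0285 and 0.0124). With miR-449a the camera call for p53 was lost after quantile normalization (0.0887), and that of other cell types with the replicate block (0.0932) and normexp (0.062). On average over the single mimics the p53 call was lost without control replicate 1 (0.0761), either miR-449a array (0.0661 and 0.0591) or miR-449b replicate 2 (0.0557), and the apoptosis call without control replicate 2 (0.0988). The seed match analysis and its alternatives were not run. Changes in genes near background are limited by the signal. The bounds given for them are lower limits with regard to dim signal only, and do not allow for the spread between arrays.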

Other observations

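The families in this part were chosen after the values were seen, and so were their camera tests, the tests of brighter members, of members not named, of array scaling and of background correction, and the test of further probes. Of 62 measured genes of the cilium and axoneme families (symbols CFAP, DNAH, DNAI, DNAAF, DRC, RSPH, TEKT, SPEF and ODAD), 30 rose and 5 fell with miR-449a, 24 and 1 with miR-449b and 26 and 1 with the mixture, but 4 and 7 with miR-449c. Camera gave adjusted p = 5.97e-08, 9.51e-08, 1.57e-07 and 0.92, against adjusted p = 0.181, 0.157, 0.138 and 0.972 with an estimated correlation. The list of 10 multiciliated cell genes fixed before the values were seen had no camera call: 1 rose and 2 fell with miR-449a (camera adjusted p = 0.896), none passed with miR-449b, 1 rose with miR-449c (camera adjusted p = 0.873), 3 rose and 1 fell with the mixture (median 0.17, camera adjusted p = 0.419), and between miR-449a and miR-449c its median was -0.23 (camera adjusted p = 0.967). CFAP206 rose by 2.32, 2.12 and 2.27 and DRC3 by 1.60, 1.43 and 1.68 with miR-449a, miR-449b and the mixture. With miR-449c they stood at 0.29 and 0.04 and did not pass. In the direct contrast 33 of the 62 were higher with miR-449a than with miR-449c and 3 lower (camera adjusted p = 2.3e-08; adjusted p = 0.153 with an estimated correlation), and 9 of 17 intraflagellar transport genes were higher, among them IFT88 (0.70) and IFT22 (0.82). The median with miR-449c was -0.08, and 0.02 after quantile normalization.

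Core histone genes fell with every mimic: of 57 measured, 40 fell with miR-449a, 40 with miR-449b, 28 with miR-449c and 41 with the mixture (camera adjusted p = 3.81e-13, 3.08e-15, 2.71e-08 and 8.94e-19; adjusted p = 0.19, 0.157, 0.341 and 0.117 with an estimated correlation). H2BC12 rose in each, by 1.19, 1.12, 1.23 and 1.22. Of 20 chemokine genes 10 rose and 1 fell with miR-449a, with CCL11 (2.82) and CXCL1 (1.79) among them, and the camera call (adjusted p = 2.8e-05) held with an estimated correlation (adjusted p = 0.03). With the mixture it held as well (9 rose, 1 fell; adjusted p = 0.0456 with an estimated correlation), while with miR-449b (7 rose, 1 fell) and miR-449c (8 rose, 3 fell) camera gave adjusted p = 0.00326 and 0.022, against adjusted p = 0.112 and 0.156 with an estimated correlation. Of 17 host genes of small nucleolar RNAs (SNHG) 14 fell with miR-449c, led by SNHG10 (-1.80), and 9 with miR-449a, and the call for miR-449c held with an estimated correlation (adjusted p = 0.0423). For the mixture (13 fell) it held too (adjusted p = 0.0456 with an estimated correlation), but for miR-449a and for miR-449b (5 fell) it did not (adjusted p = 0.074 and 0.12 with an estimated correlation). Of 50 RAB GTPases, which direct vesicle traffic, 22 rose and 1 fell with miR-449a and 20 and 2 with the mixture (adjusted p = 0.03 and 0.0456 with an estimated correlation). With miR-449b 17 rose and 1 fell and with miR-449c 13 and 3, where the camera calls were lost (adjusted p = 0.0879 and 0.0641 with an estimated correlation). These families kept the sign of their medians under each scaling tried.

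For the cilium families, dim probes are argued against by the members well above background on all arrays, whose median difference between miR-449a and miR-449c was 0.53, and by the brighter members, at 0.57, beside -0.02 and -0.01 for all genes. Normexp background correction lowered the family median from 0.60 to 0.29, so its size depends on how background is treated, but members well above background on all arrays kept 0.34 with it (SE 0.12), which argues against background as the whole cause. Array scaling is argued against by a median of 0.66 (SE 0.15) beyond the other genes nearest in mean signal. Both SEs are across genes, which are not independent replicates, so they do not measure the spread between arrays. The 58 members that no comparison names had a median of 0.57, so members that were not named differed too. So few members were left out that the median could hardly move, and this is no separate support for the pattern. A response of these families that differs between miR-449a and miR-449c remains a hypothesis from the same data, and the planned multiciliated cell list had no such call.

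The very large changes with miR-449c alone, such as those of TNFRSF4, AVP and LRRD1, had no further detected probe, and a signal specific to the probe stays open. HOXB2 had 1 further probe, which stood at -0.43 against control and did not pass, but was higher by 1.09 with miR-449a and by 1.00 with miR-449b than with miR-449c. Of 39 genes changed at least 4-fold with miR-449c, only 3 further probes were detected, and 0% of them were called in the same direction, with an exact 95% interval up to 70.8%, too few to decide. With miR-449a the share was 93.8% of 16 further probes.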
